A study of Auxenochlorella pyrenoidosa with 12 samples.

How the data were processed

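RNA of the green alga Auxenochlorella pyrenoidosa (strain label SHOU-1002) was measured by RNA sequencing of poly(A)-selected libraries. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase I, mRNA was purified with oligo(dT) beads, and libraries were made with a NEBNext Ultra kit. Poly(A) selection measures transcripts with poly(A) tails, so most organelle transcripts are poorly represented. The 12 libraries fall into 4 groups of 3, named by the NaNO3 concentration in the labels: N1.5 (1.5 g/L, the control), N1 (1 g/L), N0.5 (0.5 g/L) and N0 (0 g/L). The design text calls the libraries of a group biological repeats. The time of harvest, the culture conditions and any batch are not given in the sources used here.

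The deposited tables hold estimated counts and FPKM values for the same 16413 features in each library. Per the submitters' processing notes, Trimmomatic 0.40, Bowtie2 2.4.5 and DESeq were used, with no role or order given. The tool that turned alignments into counts, the assembly method and the annotation are not given in the sources used here. The feature names have the form that Trinity gives to assembled contigs, so a feature may be one isoform or fragment of a gene, and counts of features below are not counts of genes. Reads shared between near-identical features could have been split by the counting, which makes single features uncertain.

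The values fit estimated counts, as deposited by the authors: between 2.41 and 3.66% of a library's values were whole (within 0.001) and library totals differed. The FPKM values deposited by the authors are scaled to feature length and library total. Dividing each count by its FPKM gave one length per feature times one factor per library, so both tables carry the same information. In 733 entries the count was 0 and the FPKM above 0, with a largest FPKM of 4.14e-08. The files do not pair the feature names with gene names, functions or sequences. For this reason the gene lists fixed before the data were examined, the set tests planned on them and the tests of annotation terms could not be run, and no pathway is reported.

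Estimated counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Scaling was by TMM, with factors between 0.908 and 1.07. The filterByExpr filter by group kept 15429 features and left 984 out, and the tested features held 99.96 to 99.99% of each library's counts. All 12 libraries entered one fit with one coefficient per group and no covariate. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all tested features within a comparison. A feature is called when its adjusted p is under 0.05. The 5 comparisons were each lower NaNO3 level against N1.5, N0.5 against N1, and N0 against N0.5. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are after TMM scaling unless stated. Abundance tiers are by mean CPM over all 12 libraries, without TMM scaling, with edges at 1, 10 and 100. Group values are mean ± SD over 3 libraries. Shares of counts held by features called 2-fold or more are taken from the same libraries that selected those features. The direction of the difference in share follows from that selection, which may also enlarge it. Values of single quantities were compared by two-sided exact permutation tests, which with 3 libraries against 3 cannot go below p = 0.1.

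The rule for naming features, fixed before the data were examined, took the largest rises and falls among called features with mean CPM of at least 5, with all 3 libraries of the group on the same side of all 3 N1.5 libraries, and with a named protein. The last condition could not be applied. At most 2 rising and 2 falling features are named, all from N0 against N1.5. Ratios of pooled counts are given with 95% exact intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 in a library allows up to 3 counts, which is 0.116 to 0.136 CPM over the 12 libraries.

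Overlaps between comparisons that share libraries are set beside the number for independent lists and beside 20 simulations in which all groups were unchanged. Replicates of a group were compared by a chi-square test of their counts, and the ratio of chi-square to its degrees of freedom was between 4.75 and 16.2. No pair of libraries within a group therefore differed by counting error alone. This does not exclude a second library made from the same RNA, and libraries of different groups were not compared in this way. Principal components were computed on log2 CPM of the tested features.

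The test was tried on simulated data with the real means and library sizes. In each comparison a seeded set of 67, 67 and 66 features was changed 1.5-, 2- and 4-fold, in random directions. In the simulation of N0 against N1.5 on 15429 features, 56.7, 65.7 and 75.8% of features changed 1.5-, 2- and 4-fold were recovered. Among the 51, 44 and 43 of these features with at least 5 CPM the recovery was 74.5, 97.7 and 97.7%. Of all calls in that simulation, 6.38% were false. Far fewer features were changed there than the 57.8% called in the real comparison of N0 with N1.5. These shares therefore need not hold for the real calls. Recovery of 4-fold changes over all features fell short of the level first aimed at, and the aim was restated for features with at least 5 CPM after this had been seen.

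The alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, library totals without further scaling, no low-count filter, a mean count of at least 10, a fit of only the groups compared, the replicate number as a block, a 2-fold threshold, and limma 3.58.1 (trend) on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter. Each library was also left out in turn. Leaving out 5, and then 4, libraries together was added after seeing the data. Plots were drawn with matplotlib 3.10.9.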

Results

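Transcript levels of Auxenochlorella pyrenoidosa, a unicellular green alga, were compared between cultures at 4 NaNO3 concentrations to describe how transcription related to lipid accumulation responds to nitrogen supply. The control group N1.5 had 1.5 g/L NaNO3, and the groups N1, N0.5 and N0 had 1, 0.5 and 0 g/L, with 3 libraries each. Library totals were between 22027761 estimated counts in N1.5 replicate 3 and 24383226 in N0 replicate 1. The files do not pair features with gene names, so changes are described by direction, size, abundance and pattern over the NaNO3 levels, and nothing is said here on lipid or nitrogen metabolism genes.

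The libraries of a group resembled each other closely, and N1 lay near the control. The median Pearson correlation of log2 CPM across features, which are not independent replicates, was between 0.972 and 0.974 within each of the 4 groups. Between N1.5 and N1 it was 0.965, between N1.5 and N0.5 it was 0.923, and between N1.5 and N0 it was 0.887. The lowest value was that between N0.5 and N0, at 0.856. The first principal component held 45.4% of the variance and placed N0 and N0.5 on opposite sides of the control. The second held 24.4% and separated N0.5, and to a lesser degree N0, from N1.5 and N1.

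**Figure D1:**
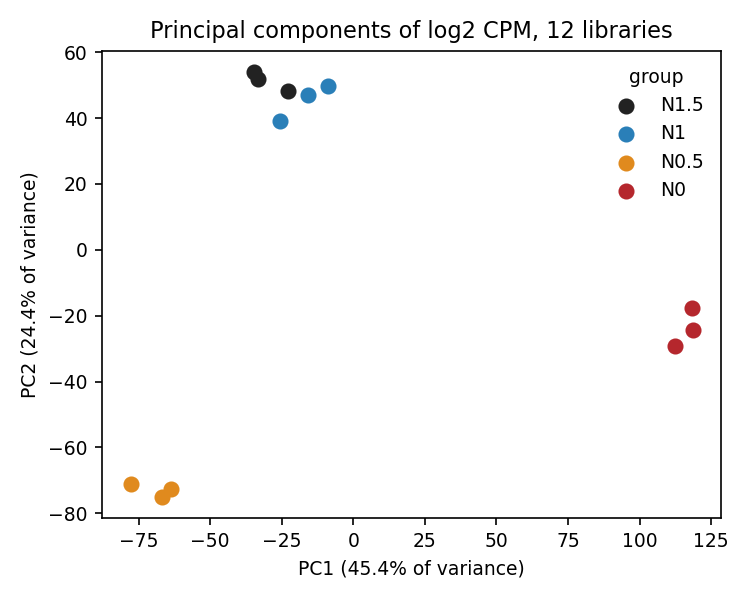
Principal components 1 (horizontal axis, 45.4% of variance) and 2 (vertical axis, 24.4% of variance) of log2 CPM, each point being one of 12 libraries and each colour a group. N1.5 and N1 lie close together, while N0.5 and N0 lie apart from them and from each other.

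The 10 most abundant features of a library took 5.16% ± 0.06 (SD, n = 3) of the counts in N1.5 and 6.93% ± 0.37 in N0. They took 5.09% ± 0.17 in N1 and 4.48% ± 0.07 in N0.5. In exact permutation tests against N1.5, p was 0.1 for N0, 0.1 for N0.5 and 0.7 for N1, where 0.1 is the smallest value the design allows. Features at 1 CPM or more without TMM scaling numbered 13231 ± 39.1 in N0.5, against 12678 ± 102 in N1.5, 12637 ± 107 in N1 and 12783 ± 188 in N0.

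The comparison of N1 with N1.5 asks what a small reduction in nitrate changed. In N1, 613 features rose and 556 fell, together 1169 or 7.58% of the 15429 tested. With library totals, falls outnumbered rises (596 up, 634 down). With TMM, 167 rose and 160 fell by 2-fold or more, and 51 rose and 58 fell by 4-fold or more. The features that rose 2-fold or more took 2.21% ± 0.09 (SD, n = 3) of the counts in N1 and 0.80% ± 0.17 in N1.5. Calls were most frequent among abundant features: at a mean of 100 CPM or more, 150 of 1991 features rose and 74 fell, whereas below 1 CPM 7 of 2450 rose and 39 fell. Falls alone were most frequent between 1 and 10 CPM, at 5.20% of features against 3.72% at 100 CPM or more. The median absolute log2 fold change was 0.57 below 1 CPM and 0.093 at 100 CPM or more. The frequency of calls is therefore no measure of the size of change. Calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This count moved with single libraries, which also lowers the number of libraries: it was 644 without N1.5 replicate 1, 689 without N1.5 replicate 2, 722 without N1 replicate 1 and 612 without N1 replicate 3, but 1056 without N1.5 replicate 3 and 1320 without N1 replicate 2. Features nearly restricted to N0 were also present at a low level in some other libraries, at a median of 1.17% of their N0 level in N1.5 replicate 3, 0.70% in N1 replicate 1, 0.99% in N0.5 replicate 1 and 1.06% in N0.5 replicate 2. With these 4 libraries left out together, chosen after seeing the data, 558 features were called in N1. A set chosen and run before it, which also left out N1 replicate 3, gave 230.

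**Figure D2:**
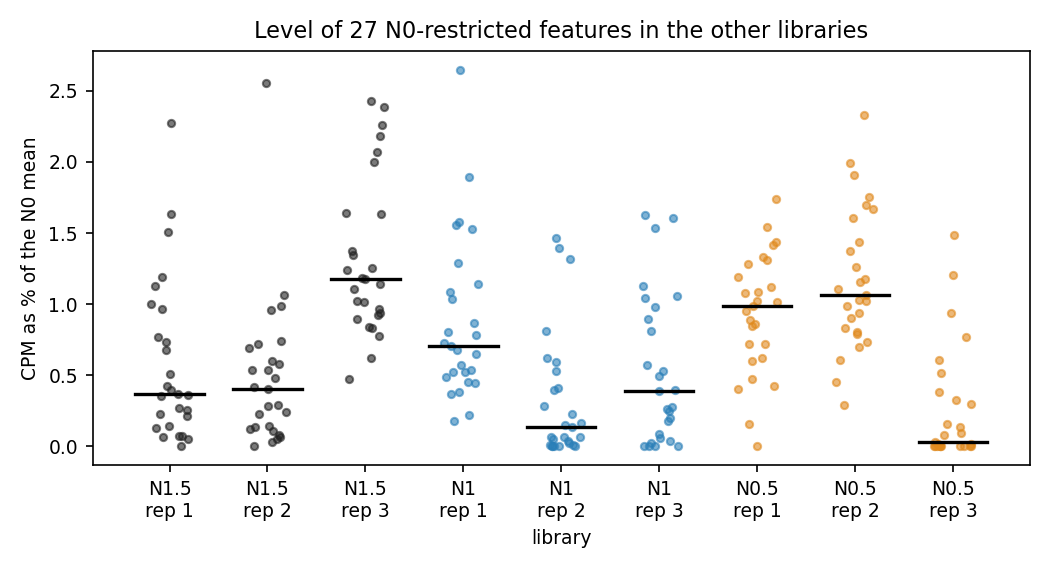
Level of 27 features nearly restricted to N0 (points) in each library of the other groups (horizontal axis), as a percentage of their mean CPM in N0 (vertical axis), with lines for the medians. Medians run from 0.035% in N0.5 replicate 3 to 1.17% in N1.5 replicate 3.

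The comparison of N0.5 with N1.5 asks what a larger reduction changed. In N0.5, 4715 features rose and 4834 fell, together 9549 or 61.9% of those tested. The near-even balance depended on scaling: rises were 49.4% of calls with TMM, 50.8% with RLE, 42.4% with library totals (4035 up, 5478 down) and 41.5, 40.6 and 43.0% in the 3 fits of FPKM values. Changes of 2-fold or more were more often rises, with 1911 up and 1249 down (1677 and 1452 with library totals), and so were those of 4-fold or more, with 635 up and 324 down (568 and 360). The features that rose 2-fold or more took 12.9% ± 0.07 (SD, n = 3) of the counts in N0.5 and 4.98% ± 0.21 in N1.5. Those that fell 2-fold or more took 3.58% ± 0.16 in N0.5 and 10.3% ± 0.02 in N1.5. At a mean of 100 CPM or more, 1010 of 1991 features rose and 558 fell, while between 10 and 100 CPM 2187 of 7950 rose and 3605 fell.

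**Figure D3:**
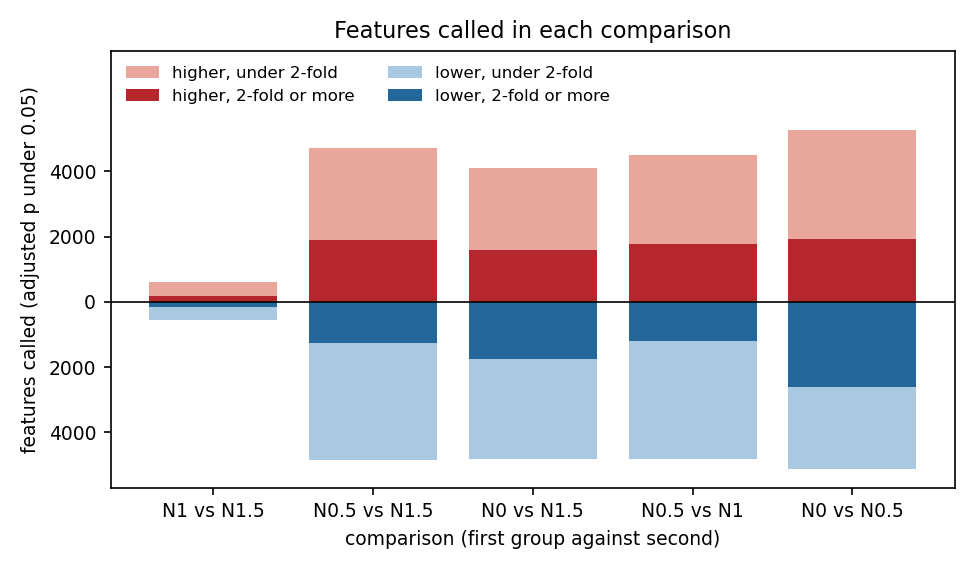
Features called by edgeR (adjusted p under 0.05) in the 5 comparisons on the horizontal axis, with those higher in the first group above 0 and those lower below 0 on the vertical axis. Dark parts of the bars are changes of 2-fold or more. N1 against N1.5 has 1169 calls and the other comparisons between 8916 and 10386.

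The comparison of N0 with N1.5 asks what the absence of added nitrate changed. In N0, 4104 features rose and 4812 fell, together 8916 or 57.8% of those tested. Falls were also more frequent at 2-fold or more, with 1591 up and 1750 down (1307 and 2243 with library totals, 1649 and 1672 with RLE). At 4-fold or more, rises were more frequent, with 782 up and 530 down (698 and 654 with library totals), and 1.39% of the tested features rose and 0.253% fell by 32-fold or more. In N0.5 against N1.5, 0.175% rose and 0.136% fell by 32-fold or more. The features that rose 2-fold or more took 19.1% ± 0.72 (SD, n = 3) of the counts in N0 and 4.75% ± 0.42 in N1.5, and those that fell 2-fold or more took 3.06% ± 0.09 in N0 and 10.3% ± 0.13 in N1.5. The balance of directions depended on scaling. Rises were 46.0% of calls with TMM, 49.1% with RLE (4393 up, 4553 down) and 49.5% with DESeq2 (4511 up, 4594 down). They were 31.8% with library totals (2914 up, 6261 down). The 3 fits of FPKM values, which are also scaled to library totals, gave 31.0, 30.7 and 32.2%. With library totals, the median log2 fold change of all tested features was -0.19, against -0.01 with TMM.

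Of the features named by rule, TRINITY_DN6553_c0_g1_i1_2 rose from 0.056 ± 0.028 CPM in N1.5 to 29.0 ± 9.48 CPM in N0 (SD, n = 3). Its log2 fold change was 8.90 with a standard error of 0.78 and an edgeR adjusted p of 2.50e-07. The pooled counts of 1927 in N0 and 4 in N1.5 gave a ratio of 463, with a 95% interval of 180 to 1700. It was also called in N1, with a log2 fold change of 4.34 and an edgeR adjusted p of 0.0234, but this call was lost in 10 of 18 alternatives, over which the adjusted p went from 0.00141 to 0.746. Over the alternatives its log2 fold change in N1 went from 0.46, on the log2(FPKM + 1) scale, to 4.89 without N1 replicate 2. It was 3.62 without N1 replicate 1 and 1.82 with 5 libraries left out for the trace of N0 features. Its counts in N1 were 52, 4 and 32 in replicates 1, 2 and 3, and replicates 1 and 3 are among those 5. In N0.5 it stood at 0.21 ± 0.20 CPM, did not pass the test against N1.5 (edgeR adjusted p 0.314) and was below N1, with a log2 fold change of -2.52 and an edgeR adjusted p of 0.0176. TRINITY_DN1624_c0_g2_i1_2 rose from 0.41 ± 0.42 CPM in N1.5 to 177 ± 14.4 CPM in N0, with a log2 fold change of 8.81, a standard error of 0.46 and an edgeR adjusted p of 1.38e-09. Its pooled counts were 11772 in N0 and 28 in N1.5, a ratio of 404 with an interval of 279 to 608. Of the 28, 19 were in N1.5 replicate 3: the log2 fold change was 9.89 without that library and 8.19 without N1.5 replicate 2. In N1 and N0.5 it stood at 0.86 ± 0.71 and 0.86 ± 0.74 CPM, and neither passed the test.

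TRINITY_DN6982_c0_g2_i1_3 fell at each NaNO3 level below the control, from 87.6 ± 10.5 CPM in N1.5 to 39.2 ± 2.93 in N1, 24.1 ± 2.98 in N0.5 and 0.48 ± 0.11 in N0 (SD, n = 3). Its log2 fold changes against N1.5 were -1.16 in N1, -1.86 in N0.5 and -7.49 in N0, with an edgeR adjusted p of 2.68e-12 in N0. TRINITY_DN6631_c1_g1_i5_2 followed the same course, from 75.6 ± 5.58 CPM in N1.5 to 36.8 ± 5.2 in N1, 24.7 ± 0.62 in N0.5 and 0.44 ± 0.18 in N0. Its log2 fold changes were -1.04, -1.61 and -7.42, with an edgeR adjusted p of 3.03e-12 in N0.

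**Figure D4:**
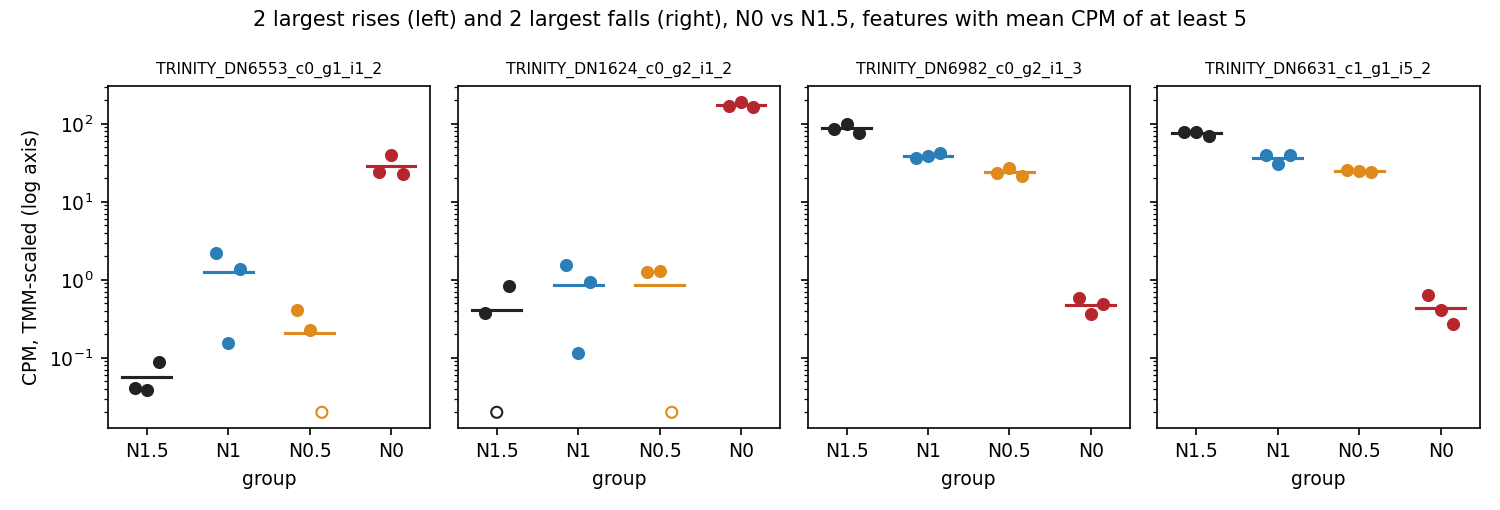
CPM after TMM scaling (vertical log axis) of the 4 named features in the 4 groups (horizontal axis), each point being one library and each line a group mean. Open points are libraries with a count of 0, drawn at a fixed low position. The left 2 features are highest in N0, and the right 2 decline from N1.5 to N0.

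The comparisons between neighbouring levels test whether successive steps differed. From N1 to N0.5, 4492 features rose and 4828 fell, of which 1772 and 1185 changed 2-fold or more. With DESeq2, rises from N1 to N0.5 were 50.6% of calls, against 48.2% here and 42.4% with library totals. From N0.5 to N0, 5276 rose and 5110 fell, together 10386 or 67.3% of those tested, and this was the largest count of the 5 comparisons. The majority direction turned with library totals (4669 up, 5648 down) and in the 3 fits of FPKM values (rises 45.6, 46.1 and 45.2% of calls). With TMM, 1919 rose and 2624 fell by 2-fold or more. With library totals the median log2 fold change of all features from N0.5 to N0 was -0.11, against -0.02 with TMM.

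Few features moved steadily with NaNO3: 55 rose and 30 fell at each of the 3 steps, where independent lists would give 61.0 and 57.6. These numbers are limited by the first step, N1 against N1.5, with its 613 rises and 556 falls. Neighbouring steps also share libraries, which pushes them in opposite directions, so independent lists are no measure of what unrelated steps would give. More often the direction turned at N0.5. Of the tested features, 3149 rose from N1 to N0.5 and then fell to N0, and 3465 fell and then rose, while 384 rose at both steps and 510 fell at both. Independent lists would give 1488 and 1651 turning features, and 1536 and 1599 continuing ones. These 2 comparisons share the N0.5 libraries, which alone pushes them in opposite directions. The covariance of their log2 fold changes was -0.98 against -0.073 in simulations without change, a difference of -0.91, and the correlation across features was -0.59 against -0.51. A real change in N0.5 that is absent in N0 enters both comparisons with opposite signs, which these simulations leave out. The covariance therefore reflects how far N0.5 stood apart, and does not by itself show an opposite response in N0. N0.5 was above both N1.5 and N0 for 3090 features, 1085 of them by 2-fold or more, and below both for 3320, of which 621 by 2-fold or more.

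Against the control, 1705 features rose in both N0.5 and N0 and 2273 fell in both, where independent lists would share 1254 and 1508. Another 1258 rose in N0.5 and fell in N0, and 1059 fell in N0.5 and rose in N0, together 2317. Independent lists would give 1471 and 1286, together 2756, a number that leaves out the pull of the shared N1.5 libraries to the same side. The share of features with the same sign was 57.9%, against 66.5% in simulations without change. The covariance of log2 fold changes was 0.32 against 0.068 in simulations without change, a difference of 0.25, and the correlation across features was 0.22 against 0.48. N1 and N0 shared 453 rises and 398 falls (163 and 173 for independent lists), and 149 features were called in opposite directions (339 for independent lists). N1 and N0.5 shared 373 rises and 238 falls (187 and 174), with 277 in opposite directions (362). The covariance exceeded that in simulations by 0.24 for N1 with N0 and by 0.11 for N1 with N0.5, while the correlations were below those in simulations, at 0.38 against 0.50 and 0.27 against 0.50. In simulations without change, the correlations and the share with the same sign come from noise of the shared controls alone. Values below them therefore do not show that the responses were less alike than unrelated ones. In all 3 comparisons with N1.5, 276 features rose and 159 fell. The simulations gave 0 shared calls by edgeR's adjusted p, which is of little use as a reference, since unchanged groups give few calls at all. The 3 control libraries cannot be split into parts of at least 2 each, so part of the excess over independent lists may come from the shared controls.

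**Figure D5:**
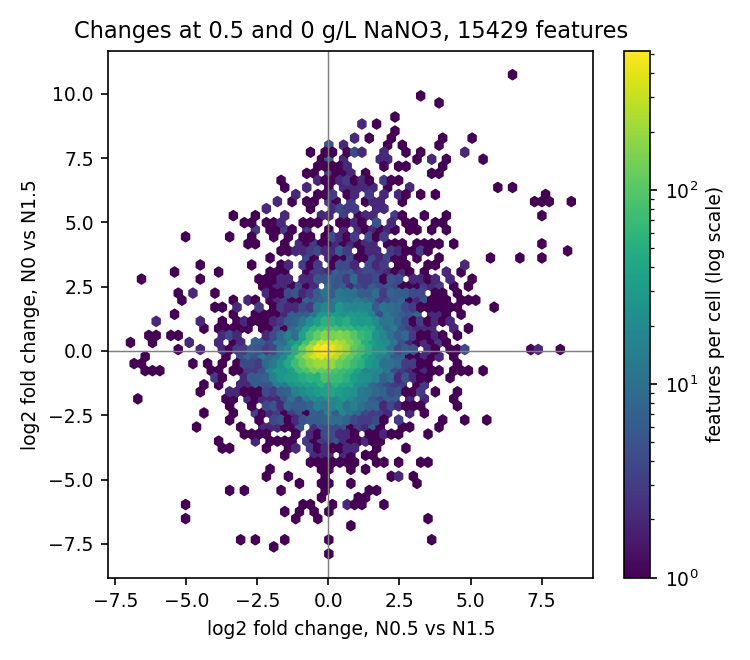
Log2 fold change in N0.5 (horizontal axis) and N0 (vertical axis), both against N1.5, for the 15429 tested features, with colour giving the number of features per cell on a log scale. Features lie in all 4 quadrants, and 2317 were called in opposite directions.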

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

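The 2317 features called in opposite directions in N0.5 and N0, each against N1.5, were singled out because the direction of change differed between the 2 groups. That all of them also pass the direct test of N0 against N0.5 follows from this selection and adds no evidence. Independent lists of these sizes would give 2756 opposite calls, but the shared N1.5 libraries push both comparisons to the same side, so this is no measure of what unrelated responses would give. Of the 2317, 1258 were higher in N0.5 and lower in N0, and 1059 the reverse. Scaling was tested as the cause: 1777 of the 2317 (76.7%) were again called in the same opposite directions with library totals and 2227 (96.1%) with RLE size factors. This argues against the choice among these scalings as the whole cause. RLE is a weak test, since the median log2 fold change of all features in N0 was 0.019 with it and -0.015 with TMM. With library totals that median was -0.19. A larger shift between groups was not tested, and only 361 of the 2317 changed 2-fold or more in both comparisons. A trend with feature length and abundance was tested next: after each library's smooth trend with both was removed, 1663 (71.8%) were again called so, which argues against such a trend as the whole cause. The rest lost a call under these corrections, while other features gained one: the totals of opposite calls were 2205 with library totals, 2357 with RLE and 2385 after the trend correction. Which features show the pattern may therefore depend on scaling or trend more than their number does. A culture, harvest or sequencing batch cannot be told apart from the groups, since 0 labels name one. A different response to 0.5 and to 0 g/L NaNO3 stays open as a biological explanation, and so does a difference in growth stage at harvest, neither of which was tested.

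Each comparison was set against the other splits of its 6 libraries into 3 and 3. In each, only the real grouping, 1 of 10 splits, called as many features as were observed, and 10 splits are too few for a share under 0.05. Every other split mixes libraries of both groups, so a difference between the groups widens the spread within each part and lowers the calls. The counts of the other splits are therefore no measure of what unchanged groups would give. By edgeR, the real grouping called 1169 features in N1 against N1.5 and the highest other split 0. At an unadjusted p under 0.05 these were 3212 for the real grouping and up to 2243 for the others. The 2243 came from the split that set N1.5 replicate 3 and N1 replicates 1 and 3 against the rest, and the remaining splits gave 258 to 952. These 3 libraries are in the set of 5 first left out for the trace of N0 features. For N0.5 against N1.5 the values were 9549 and 0 (unadjusted 10055 and up to 359), for N0 against N1.5 8916 and 0 (9505 and 608), for N0.5 against N1 9320 and 1 (9923 and 420), and for N0 against N0.5 10386 and 0 (10778 and 334). DESeq2 was not run on these splits.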

How the results depend on the processing

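Leaving out 5 or 4 libraries together was chosen after the data were seen. No named feature changed sign in a comparison that called it. Of the alternative counts, 86 stayed within 1.5 times the reported one and 15 did not. The 15 came from the 2-fold threshold, from N1 against N1.5 with 1 library left out, and from leaving out 5 or 4 libraries. The majority direction of calls did turn, for example with library totals in N1 against N1.5 (596 up, 634 down) and N0 against N0.5 (4669 up, 5648 down), and with RLE in N0.5 against N1.5 (4847 up, 4703 down). Features called 2-fold or more were 327 in N1 against N1.5, 3160 in N0.5 against N1.5, 3341 in N0 against N1.5, 2957 in N0.5 against N1 and 4543 in N0 against N0.5. With that threshold, 98 features were called the same way in all 3 comparisons with N1.5 (435 without it), 782 the same way in N0.5 and N0 (3978) and 361 in opposite ways (2317). These counts are lower by construction.

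With 1 library left out, N1 against N1.5 gave 612 to 1320 calls, with 1169 reported. It was 644 without N1.5 replicate 1, 689 without N1.5 replicate 2, 722 without N1 replicate 1 and 612 without N1 replicate 3. The other ranges were 8838 to 8993 for N0.5 against N1.5, 8248 to 8544 for N0 against N1.5, 8648 to 9108 for N0.5 against N1 and 9861 to 10216 for N0 against N0.5. Leaving out 5 libraries (N1.5 replicate 3, N1 replicates 1 and 3, N0.5 replicates 1 and 2) gave 230 calls in N1 against N1.5 and 5648 in N0.5 against N1. It left 1 library in N1 and in N0.5, which was assumed to vary like the others. Leaving out 4, with N1 replicate 3 kept, was tried second and gave 558 and 6823. How far fewer libraries alone account for these losses was not tested. The calls of all 4 named features in N0 held in 19 of 19 alternatives, but the size of the changes did not: on the log2(FPKM + 1) scale, which understates changes of low features, TRINITY_DN6553_c0_g1_i1_2 was at 3.29 (6.22 with 0.1), TRINITY_DN1624_c0_g2_i1_2 at 7.36, TRINITY_DN6982_c0_g2_i1_3 at -6.06 and TRINITY_DN6631_c1_g1_i5_2 at -5.60.

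The replicate numbers do not pair the samples: over 18 same-numbered pairs the correlation of deviations was between -0.067 and 0.070, and 3 of 12 libraries correlated best with their own number. With the replicate block the counts were 1184, 9542, 8924, 9348 and 10392. The planned tests of gene lists and annotation terms were not run, since the files do not pair features with names. Depth limits the least abundant features, whose changes the simulations recovered less often.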

Other observations

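The tests on traces of N0 features and on feature names were chosen after these patterns had been seen, and their limits were written with some of the values that bear on them in view. Intervals of medians, excesses and gaps below are bootstraps over features, which vary together, and do not measure the spread between libraries. Features of low abundance moved mainly upward in N0.5: below a mean of 1 CPM, 548 of 2450 rose and 121 fell against N1.5, and between 1 and 10 CPM 970 of 3038 rose and 550 fell. Features whose name ends in the number 2 went the other way, with 4.62% up and 14.8% down below 1 CPM and 16.1% up and 31.4% down between 1 and 10 CPM. Over all names, the numbers in N0 for these tiers were 306 up and 184 down, and 726 up and 787 down. These totals mixed names that went different ways. Below 1 CPM, features up and down in N0 were 18.2 and 3.50% for number 1, and 11.3 and 13.1% for number 2. For number 3 they were 2.72 and 11.3%, and for number 4 17.9 and 2.89%. Between 1 and 10 CPM they were, in the same order, 29.5 and 16.7%, 24.9 and 28.3%, 12.8 and 38.3%, and 28.2 and 21.2%. Of the features at 1 CPM or more in a group with at least 90% of the sum of group means in that group, 131 belonged to N0 and 11 to N0.5.

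In 27 features with at least 50 CPM in N0 and under 3% of that level in each other library, the remaining level differed between libraries of the same group. The median was 0.37, 0.40 and 1.17% of the N0 level in N1.5 replicates 1, 2 and 3, 0.70, 0.14 and 0.39% in N1, and 0.99, 1.06 and 0.035% in N0.5. N1 replicate 3 was among the 5 libraries first left out, although its median is no higher than that of N1.5 replicate 2. A candidate explanation is carry-over of N0 material or reads. It predicted an excess in 204 other features, those at least 4-fold higher in N0 that also reached 50 CPM there. In N1.5 replicate 3 they would exceed the other N1.5 replicates by 0.5 to 2 times its trace excess of 0.85%. Unlike the 27, each of the 204 had at least 3% of its N0 level in some other library. Larger differences between replicates can therefore follow from this selection alone. The excess was 2.51% (95% bootstrap interval 2.23 to 2.95), which is above that range and does not decide. N1.5 replicate 2, whose trace is 0.40%, deviated by -2.06%. Each library is set against the other replicates of its group, so deviations within a group offset each other. That of replicate 2 is therefore in part the mirror of replicate 3 and is not separate evidence. The same test was then run on each library outside N0. The ratio to the trace excess was 1.20 and 0.81 in N0.5 replicates 1 and 2, inside the range although the interval of the excess in replicate 1 (-0.011 to 0.37%) includes 0, and 2.86 in N1 replicate 1, above it. In the libraries whose trace lay below that of their group it was 1.28 and 4.45 in N1.5 replicates 1 and 2, 6.08 and -4.68 in N1 replicates 2 and 3, and 0.77 in N0.5 replicate 3, so the libraries give no single answer. Ratios within a group are not independent, for the reason given above.

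A partial N0-like response of the culture is the other explanation for the trace. Over 530 features at least 4-fold lower in N0, the median log2 ratio of N1.5 replicate 3 to the other N1.5 replicates was 0.0083 (interval -0.016 to 0.045). The limit written for this test, -0.05, would by itself exclude such a response. That limit was too coarse: a response of the size of the trace would lower these features by a log2 of only -0.012, which lies within the interval. Carry-over of the same size would dilute these features by the same amount. The test therefore cannot separate carry-over from a partial response, whatever its outcome. In N1 replicate 1 the median was -0.038 (interval -0.065 to -0.017), the direction that both a partial response and carry-over predict. But N1.5 replicate 2, without an excess of trace, also lay below 0, at -0.028 (interval -0.054 to -0.0010). In N0.5 replicates 1 and 2, which had an excess of trace, the medians were 0.00065 and -0.0099, with intervals that include 0. N1 replicate 2, without an excess of trace, was at 0.031 (interval 0.0040 to 0.068). This may in part mirror N1 replicate 1, since each is in the reference of the other. The intervals of the remaining libraries include 0. Carry-over and a partial response therefore cannot be told apart here.

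The balance of calls differed with the last number of the feature name, which runs from 1 to 4 and whose meaning is not given in the sources used here. In N0 against N1.5, rises were 52.2, 44.7, 35.9 and 51.3% of calls for the numbers 1, 2, 3 and 4, and in N0.5 against N1.5 they were 54.8, 36.0, 50.5 and 55.4%. One candidate explanation is that the numbers mark separate assemblies, some made without reads of every group. The number 3 made up 4.58% (exact 95% interval 1.70 to 9.70) of the 131 features nearly restricted to N0, against 25.5% of all tested features. This does not decide, because all 131 are themselves rises in N0, the measure in which the pattern was seen, so separate assemblies cannot be told apart from other explanations. Different abundance of the numbered sets was tested as well: the share of features that rose in N0 was lower for number 3 than for number 1 in 3 of 4 abundance tiers (2.72 and 18.2%, 12.8 and 29.5%, 23.5 and 30.6%, then 43.1 and 42.5% at 100 CPM or more). The limit first written asked for all 4 tiers. At equal make-up by tier, a measure added later, the gap was 9.37 percentage points (bootstrap interval 7.51 to 11.1) against 9.49 without that correction. This argues against different abundance as the cause of the gap between numbers 1 and 3 in N0. The other differences, such as that of number 2 in N0.5, were not tested in this way. No biological explanation was tested for either pattern.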
